A study of Danio rerio with 14 samples.

How the data were processed

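ATAC-seq libraries of adult zebrafish cardiomyocytes were analysed from the deposited processed tables only. Per the labels, gata4:EGFP+ and myl7:nucDsRed+ cells were isolated by fluorescence-activated sorting and the other groups by density gradient centrifugation, with 50000 cells per reaction for the junba and junbb libraries and 5000 for all others. Injured samples were collected 4 days after cryoinjury and overexpressing samples 7 days after induction. A-Fos(+) fish received 4-hydroxytamoxifen and A-Fos(-) fish ethanol vehicle, and A-Fos cardiomyocytes came from the wound border. Each library pools 6 hearts.

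Per the submitters' processing notes, reads were handled with Trimmomatic 0.36, STAR 2.6.1d, Picard 2.18.16, MACS2, deepTools 2.5.7, DESeq2 1.18.1 and DESeq, on builds danRer11 and GRCz11. The notes do not state the mapping filters, the shift of reads to the transposase cut site, the peak thresholds or the way of background correction. The values of both tables are a score made by the authors: background-corrected reads per peak, divided by size factors and rounded to whole numbers, each table by itself. Values were therefore compared only within a table. The authors' annotation gives 1 gene for part of the peaks, the distance of the peak centre to its transcription start site in bp without sign, and, per the file headers, the fraction of the peak that overlaps the gene body. Whether coordinates count from 0 or 1 is not stated, so they are printed as deposited.

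Values are rounded, so raw reads could not be recovered and no count model was fitted. The value of 1 read, the step between the values of a library, was estimated from the spacing of its values, tested on simulated data with 8 steps (largest error 0.245%). Steps ran from 0.427 in A-Fos(-) replicate 1 to 2.885 in A-Fos(+) replicate 3, both just outside the simulated range. The share of the variation in spacing that the step explained ran from 0.583 to 0.996 in the same libraries, so the read numbers are approximate. Estimated nuclear reads in peaks were 1451740 and 993104 for gata4:EGFP+ replicates 1 and 2, 802252 and 1020285 for myl7:nucDsRed+, 613592 and 468462 for junba, 851110 and 916188 for junbb, 567389, 307073 and 129391 for A-Fos(+), and 811239, 521841 and 233648 for A-Fos(-). The mitochondrial peak, left out of every fit, held 72.7 ± 1.01% of the summed values in gata4:EGFP+, 85.0 ± 2.29% in myl7:nucDsRed+, 87.8 ± 0.110% in junba and 84.2 ± 2.00% in junbb libraries (mean ± SD, n = 2), and 90.5 ± 4.72% with and 85.0 ± 4.45% without A-Fos (n = 3, difference 5.44 points, exact permutation test, two-sided, p = 0.3, smallest possible p 0.1).

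Peaks with a mean value of at least 10 were tested with limma 3.58.1 in R 4.3.3 on log2(value + 5), with empirical Bayes moderation, trend and robust estimation, two-sided, and called at a Benjamini-Hochberg adjusted p under 0.05. The shared table was fitted with all 4 groups (8 libraries), so that the groups share 1 estimate of spread, and the A-Fos table with 3 against 3. The comparisons were gata4:EGFP+ minus myl7:nucDsRed+ (regeneration), junba minus myl7:nucDsRed+, junbb minus myl7:nucDsRed+, junba minus junbb, and A-Fos(+) minus A-Fos(-). The model was tested on simulated data of the same depth with 2-fold and 4-fold changes: 70.4%, 68.1%, 68.8% and 73.1% of 4-fold changes and 11.7%, 12.6%, 10.6% and 11.6% of 2-fold changes were recovered for regeneration, junba, junbb and A-Fos, with 4 of 84, 10 of 86, 3 of 79 and 3 of 82 calls false. Few peaks were changed in the simulated data, 94 by 2-fold and 98 by 4-fold of 14667 tested for regeneration. The share recovered also depends on how many peaks change, which was not varied. The median half-width of the 95% interval of a log2 change was 0.79 in the shared table and 0.72 in the A-Fos table. Tables were read with Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and figures drawn with Matplotlib 3.10.9.

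Before the data were examined, 16 gene lists, the comparisons, the tests and the rule for named genes were fixed. The lists are sarcomere, AP-1 subunits, actin protrusion, extracellular matrix and adhesion, cardiac development and regeneration, cell cycle, calcium handling and conduction, oxidative metabolism, glycolysis, immediate early genes without AP-1, and, as markers of other cell types, endothelial and endocardial, epicardial and fibroblast, leukocyte, erythroid and thrombocyte, smooth muscle, and neural and Schwann. The list of immediate early genes without AP-1 was planned as a mark of the stress of isolation. Lists with at least 2 peaks were tested with camera, preset correlation 0.01 and again an estimated one, adjusted over the lists of a comparison. Camera compares the peaks of a list with all other tested peaks. The rule names, among called peaks whose groups do not overlap and whose mean is at or above the median, the 10 largest log2 changes in each direction, 1 peak per gene with a symbol. Where under 10 pass, it names those and the next by p, up to 5. It adds the peak of smallest p per list and direction, and the peaks of junba, junbb, gata4 and myl7. KEGG terms with at least 5 genes were tested by the exact hypergeometric test among 2025 genes with a tested peak and a term.

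Peaks of both tables were matched where they share at least 50% of the shorter peak, which 6003 of 6012 tested A-Fos peaks did. Overlaps between comparisons with shared controls were set beside n1 × n2 / N and beside 100 simulations with the same controls and no effects. Each simulation took the observed numbers of peaks with the smallest p in each direction, whether or not they passed the threshold. Location near a start site was tested with Fisher's exact test, two-sided.

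Alternatives tried were pseudocounts 1 and 20, no filter and a mean of at least 30, quantile normalization, equal totals over tested peaks, a replicate block, only the 2 groups compared, other overlap rules, an estimated correlation and each library left out. Added after the data were seen were array weights, centring on peaks within 500 bp of a start site, leaving out peaks wider than 2000 bp, and leaving out both A-Fos libraries of a replicate number. The planned tests of 13 sequence motifs, AP-1 among them, were not run, since no genome sequence was at hand.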

Results

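Chromatin accessibility was profiled by ATAC-seq in cardiomyocytes of adult zebrafish hearts, in 14 libraries of 6 groups. The series addresses AP-1, the dimeric transcription factor formed by Fos and Jun proteins, in heart regeneration. Regenerating gata4:EGFP+ cardiomyocytes, collected 4 days after cryoinjury, uninjured myl7:nucDsRed+ cardiomyocytes and uninjured cardiomyocytes overexpressing junba or junbb gave 2 libraries each and share 1 table of 16610 peaks. A second table of 6339 peaks holds 3 libraries each of injured cardiomyocytes with and without induced A-Fos, a dominant-negative protein that binds Jun partners and keeps them off DNA. Accessibility is given in the authors' normalized counts, a peak is named by the gene the authors assigned to it, and log2 changes are estimates ± SE from limma (two-sided, Benjamini-Hochberg adjusted p). The labels state 6 hearts per pool and do not say whether replicates came from separate animals beyond that, so limma p-values measure the spread between these samples. Fisher's exact and hypergeometric tests take peaks or genes as their units, and camera with the preset correlation compares peaks. Their p-values do not measure the spread between samples. List members outside the rule for named genes were chosen as examples after their values were seen.

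Regenerating cardiomyocytes were more accessible than uninjured ones beside genes such as cd63, socs3a and anln, and less accessible at sarcomere genes such as myl7 and ttn.1. The groups were sorted on different reporters, and no uninjured gata4:EGFP+ or injured myl7:nucDsRed+ library is in the series. Injury therefore cannot be separated from the sorted population in this comparison. The peak inside cd63 (ENSDARG00000025147, 23:32070968-32071370), a tetraspanin of late endosomes, held 74.5 ± 9.19 normalized counts in gata4:EGFP+ against 4.5 ± 0.707 in myl7:nucDsRed+ libraries (mean ± SD, n = 2), a log2 change of 3.06 ± 0.37 (adjusted p = 5.14e-05). A peak 2981 bp from the start of socs3a (ENSDARG00000025428, 3:57422663-57423296), which encodes an inhibitor of JAK-STAT signalling, rose by 2.42 ± 0.31 (adjusted p = 7.88e-05, 151 ± 2.83 against 24.5 ± 6.36, n = 2). Also higher were ugdh (2.77), whose enzyme makes the UDP-glucuronate of hyaluronan, anln (2.76), the anillin of the cytokinetic ring, glis2a (2.69), a zinc finger factor, the tumour necrosis factor gene tnfb (2.64), and nfkbiaa (2.32), an inhibitor of NF-kappaB. The peaks of ms4a17a.14 (2.67), mtus1b (2.55) and glrbb (2.41), a glycine receptor subunit, completed the 10 largest increases by the naming rule. The promoter peak of myl7 (ENSDARG00000019096, 8:40464789-40465383), the cardiac myosin regulatory light chain, changed by −2.70 ± 0.34 (adjusted p = 6.78e-05), from 314 ± 1.41 to 45 ± 14.1 (n = 2). That promoter also drives the reporter used to sort the uninjured cells. Further decreases were seen at mif4gdb (−2.38), scp2a (−2.33), a sterol carrier, the ribosomal stalk gene rplp1 (−1.99), itm2cb (−1.99) and the galectin gene lgals8b (−1.96). Lower peaks were also named at the kinase genes sbk3 (−1.96) and ttbk1b (−1.79), the titin gene ttn.1 (−1.94), and ppargc1a (−1.90), a master regulator of mitochondrial biogenesis.

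Of 14776 peaks tested, 1818 were higher in regenerating cardiomyocytes (65.0% of calls, median log2 change 1.63) and 977 were lower (median −1.18). Leaving out gata4:EGFP+ replicate 1 left 345 higher and 177 lower, gata4:EGFP+ replicate 2 328 and 129, myl7:nucDsRed+ replicate 1 1039 and 357, and myl7:nucDsRed+ replicate 2 1075 and 295. Equal totals over tested peaks gave 2163 higher and 300 lower (87.8% higher) and moved the median change of all peaks from −0.06 to 0.15. Centring on peaks near transcription start sites gave 2333 and 429 (84.5% higher, median 0.15). Quantile normalization gave 1822 and 1418 (56.2% higher), and testing only peaks with a mean of at least 30 gave 352 and 488 (41.9% higher).

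Accessibility fell at 11 of 37 peaks of sarcomere genes. These peaks lie at 25 of the 51 genes of the list, and 0 rose and 26 were not called (0 higher and 13 lower adjusted over the list alone). Their median log2 change was −0.71 (camera, adjusted p = 2.8e-05, and adjusted p = 0.49 with an estimated correlation). The declines at myl7 and ttn.1 kept their calls whichever of the 4 libraries was left out, whereas those at actc1a (cardiac actin, −1.86), tnnc1a (troponin C, −1.36) and 7 others did not. Oxidative metabolism followed, with 0 higher and 9 lower of 20 peaks (the same adjusted over the list alone, median −0.60, adjusted p = 0.0093, and adjusted p = 0.45 with an estimated correlation). Its lower members included ppargc1a, the estrogen-related receptor gene esrrga (−0.91), the muscle creatine kinase gene ckma (−1.09) and ogdha (−1.08) of the citric acid cycle. Glycolysis gave 1 higher and 4 lower of 31 peaks (0 and 4 adjusted over the list alone, median −0.39, adjusted p = 0.0093, and adjusted p = 0.43 with an estimated correlation). The phosphoglycerate mutase gene pgam2 fell (−1.65, adjusted p = 0.0011), as did aldoaa, ldhba and ldha, while the hexokinase gene hk2 rose (1.17, adjusted p = 0.0497). Calcium handling and conduction gave 1 higher and 3 lower of 16 peaks (1 and 4 adjusted over the list alone, median −0.73, adjusted p = 0.030, and adjusted p = 0.49 with an estimated correlation). Its lower peaks belonged to calm1a (calmodulin, −0.93), the sarcoplasmic calcium pump gene atp2a2a and the calsequestrin gene casq2, and its higher peak to the calcium channel subunit gene cacnb2a (1.58). Quantile normalization ended the list calls of calcium handling (adjusted p = 0.11), glycolysis (0.095) and oxidative metabolism (0.095). Calcium handling also lost its call without gata4:EGFP+ replicate 1 (0.070) or myl7:nucDsRed+ replicate 2 (0.12). Glycolysis lost it without myl7:nucDsRed+ replicate 2 (0.058).

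Among the AP-1 subunits, 3 of 19 peaks rose and 2 fell (5 and 2 adjusted over the list alone, median 0.35, adjusted p = 0.32). The 3 that rose lay at jdp2a (1.27, adjusted p = 0.0155), a repressive AP-1 partner, at maff, and downstream of junbb (0.83, adjusted p = 0.0301, 3:7653992-7654370). The 2 that fell lay within junbb (−1.73, adjusted p = 8.85e-05) and at jun, and the peaks of junba were not called (−0.38 and 0.91, adjusted p = 0.297 and 0.0625). In the list of cardiac development and regeneration 2 of 28 peaks rose and 3 fell (2 and 4 adjusted over the list alone, median −0.25, adjusted p = 0.31). Those that rose lay at socs3a and ankrd1a, a stretch-responsive ankyrin repeat gene, and those that fell at the cardiac transcription factor genes tbx20 (−1.32), tbx5b and gata5. The promoter peak of gata4, another of these factors, was not called (0.46, adjusted p = 0.342). For the cell cycle 4 of 30 peaks rose and 0 fell (the same adjusted over the list alone), at the cyclin genes ccnb1 and ccnd1 (1.83) and 2 peaks of anln. The median of that list was −0.11, its mean 0.12 and its camera direction down (adjusted p = 0.98). The helicase gene mcm4 was not called (−0.75, adjusted p = 0.0697). Extracellular matrix and adhesion gave 5 higher and 2 lower peaks of 16, the same adjusted over the list alone (median 0.05, adjusted p = 0.56). The risers were sparc (2.45), the fibronectin gene fn1a, the collagen genes col5a2a and col1a2, and timp2b, and both lower peaks belonged to the integrin gene itga5 (−1.86 and −1.64). In KEGG pathways the higher set held 6 of 21 genes of ECM-receptor interaction against 0.871 by chance (exact hypergeometric test, adjusted p = 0.0193), the only one of 138 terms past the threshold. No term passed for the lower set (smallest adjusted p = 0.281). Actin protrusion gave 1 higher, flnb (1.66), and 1 lower, actn1 (−1.24), of 29 peaks, the same adjusted over the list alone (median −0.36, adjusted p = 0.075). Without myl7:nucDsRed+ replicate 1 the list passed with the preset correlation (median −0.51, adjusted p = 0.020) but not with an estimated one (adjusted p = 0.39). Immediate early genes other than AP-1 gave 2 higher and 3 lower of 35, the same adjusted over the list alone (median −0.23, adjusted p = 0.31). These were the heat shock genes hsp70.1 (2.24) and hsp70.2, and dusp1 (−1.46), a MAP kinase phosphatase gene, gadd45ba and ier5.

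No list of markers of other cell types passed in this comparison, and each gave the same counts adjusted over the list alone. Endothelial and endocardial markers gave 3 higher (klf2a at 1.42, nfatc1 and sox18) and 0 lower of 13 peaks (median 0.40, adjusted p = 0.14). Epicardial and fibroblast markers gave 1 higher (col6a1, 2.705) and 1 lower (tgfb3, −0.73) of 5 (median 0.53, adjusted p = 0.31), and leukocyte markers 1 higher (irf8, 1.98) of 3 (median 0.22, adjusted p = 0.31). In erythroid and thrombocyte markers sptb fell (−0.97, 1 of 2 peaks, list median −0.54, adjusted p = 0.31). In smooth muscle markers smtnb fell (−1.68, 1 of 2, median −0.64, adjusted p = 0.55), and the single neural and Schwann peak, at elavl4, rose (1.68). The list members tcap (0.78, adjusted p = 0.16), hadhaa (0.32, adjusted p = 0.486), cdh5 (−0.35, adjusted p = 0.602) and cnn1b (0.40, adjusted p = 0.531) were not called.

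Of 66 list peaks called in regeneration 14 kept their calls whichever library was left out and 52 did not. Peaks named by the rule lost or gained calls as follows. Without gata4:EGFP+ replicate 1 the adjusted p was 0.186 at jdp2a, 0.127 at tbx20, 0.158 at cacnb2a, 0.139 at hk2, 0.192 at tgfb3, 0.0521 at irf8, 0.23 at sptb, 0.0823 at elavl4 and 0.109 downstream of junbb. Without gata4:EGFP+ replicate 2 it was 0.0836 at jdp2a, 0.333 at hk2, 0.107 at tgfb3, 0.106 at sptb, 0.0958 at elavl4 and 0.264 downstream of junbb. It was also 0.129 at sbk3, 0.171 at flnb, 0.0897 at actn1, 0.157 at itga5, 0.133 at calm1a, 0.0717 at klf2a and 0.326 at smtnb. When myl7:nucDsRed+ replicate 1 was left out it was 0.0841 at tgfb3, 0.108 at sptb, 0.0758 downstream of junbb, 0.0711 at itga5, 0.0625 at calm1a and 0.0562 at smtnb. The distal junba peak then passed (0.0466). With myl7:nucDsRed+ replicate 2 left out it was 0.0974 at jdp2a, 0.102 at tbx20, 0.0857 at cacnb2a, 0.379 at hk2, 0.119 at tgfb3 and 0.11 at sptb. It was 0.0579 at elavl4, 0.155 downstream of junbb, 0.0648 at sbk3, 0.0557 at actn1 and 0.162 at smtnb. Whichever of the 4 libraries was left out, the list peaks higher at sparc, socs3a, ccnd1, 1 peak of anln (2.76), col6a1, hsp70.1 and hsp70.2 kept their calls. So did those lower at myl7, ttn.1, 1 peak of ppargc1a (−1.90), pgam2, gadd45ba, dusp1 and within junbb.

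**Figure D1:**
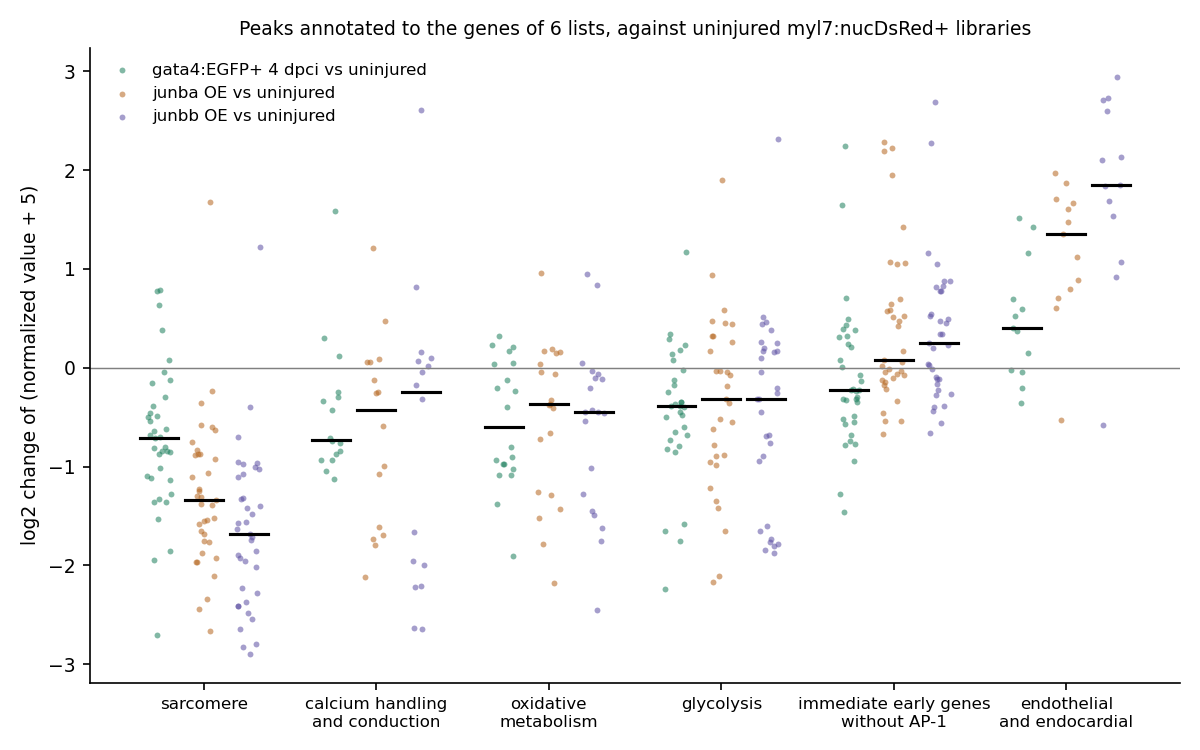
Log2 changes in accessibility of the peaks of 6 gene lists in the regeneration, junba and junbb comparisons, each against uninjured myl7:nucDsRed+ cardiomyocytes. Each point is 1 peak and the black line is the median of the list.

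Peaks that gained accessibility in regeneration lay away from promoters. Of the 1818 higher peaks 7.98% had their centre within 500 bp of an annotated transcription start site, against 42.3% of the peaks not called (odds ratio 0.118, Fisher's exact test, two-sided, p = 1.92e-210). The 977 lower peaks did not differ detectably from those not called (45.0%, odds ratio 1.12, exact p = 0.0991). A gene was assigned to 22.8% of higher, 62.9% of lower and 57.1% of uncalled peaks. The peaks at cd63, socs3a and anln, 5001, 2981 and 5161 bp from the start sites, are of the distal kind, whereas those at rplp1, scp2a and pgam2, at 49, 18 and 31 bp, are promoter peaks. Under junba and junbb overexpression the lower peaks were mostly distal. They had 13.3% and 12.98% near a start site, against 42.7% and 44.4% of those not called (odds ratios 0.206 and 0.187, Fisher's exact test, p = 4.44e-177 and 7.86e-203). The higher junbb peaks were depleted near start sites to a lesser degree (36.1%, odds ratio 0.708, Fisher's exact test, p = 2.58e-11), and the higher junba peaks did not differ detectably from those not called (44.5%, odds ratio 1.07, exact p = 0.193).

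**Figure D2:**
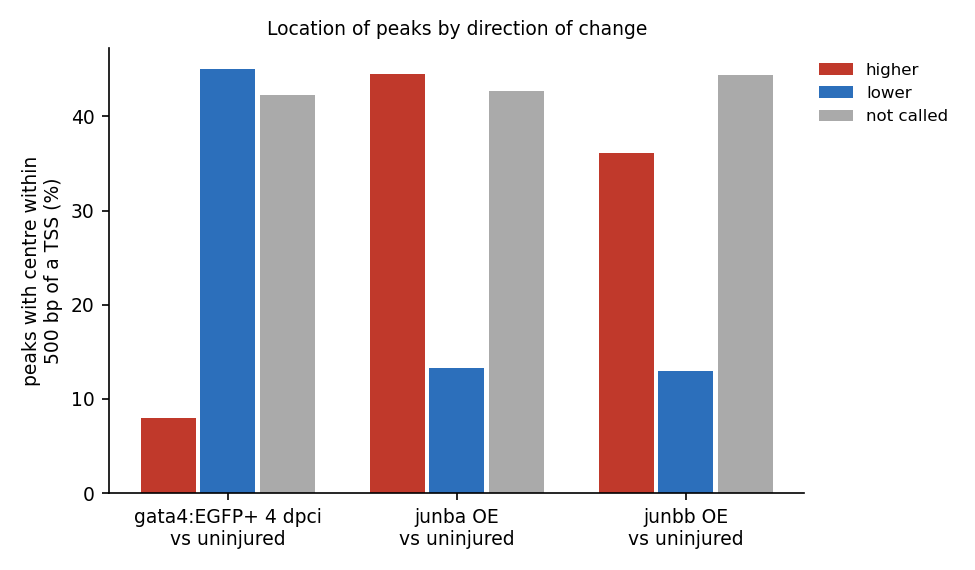
Percent of tested peaks whose centre lies within 500 bp of an annotated transcription start site, among peaks called higher, called lower or not called, in the regeneration, junba and junbb comparisons.

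Cardiomyocytes overexpressing junba differed from uninjured myl7:nucDsRed+ cardiomyocytes by lower accessibility at muscle genes such as mylk2 and flnca and higher accessibility at endothelial genes such as ptprb and clec14a. The labels give density gradient isolation and 50000 cells per reaction for these libraries, and sorting and 5000 cells for the uninjured ones, so isolation cannot be separated from overexpression in this comparison. The largest increases named were tnfaip8l3 (2.92 ± 0.41, adjusted p = 6.4e-05), ptprb (2.68), the vascular endothelial receptor phosphatase, knstrn (2.65) of the kinetochore, vap (2.64) and clec14a (2.48), an endothelial C-type lectin. Next were the endonuclease gene slx1b (2.46), wbp2nl (2.46), ms4a17a.14 (2.45), ubb (2.42) and vamp5 (2.41). The wide promoter peak of ubb (ENSDARG00000093313, 5:42091343-42093982), a ubiquitin gene, held 996 ± 31.8 normalized counts against 183 ± 24 (n = 2, adjusted p = 7.67e-07). The promoter of ubb is in wide use in zebrafish transgenes, and the labels do not name the constructs. The largest decreases named were zbtb12.1 (−2.99), the muscle myosin light chain kinase gene mylk2 (−2.79), the small heat shock gene hspb6 (−2.73), apobec2a (−2.69) and the filamin C gene flnca (−2.66). They were followed by lhfpl2a (−2.49), arhgap20b (−2.48), the Z-disc gene ldb3a (−2.44), tbx5b (−2.41) and the fibulin gene efemp2a (−2.35). In all 1515 peaks were higher (39.3% of calls, median log2 change 1.31) and 2342 lower (median −1.46). Omitting myl7:nucDsRed+ replicate 1 left 882 higher and 1421 lower peaks, myl7:nucDsRed+ replicate 2 932 and 1039, and junba replicate 2 929 and 1567. Omitting junba replicate 1 instead raised both counts. Fitting only the 2 groups compared gave 917 higher and 1715 lower peaks. Centring on peaks near start sites gave 1115 and 2912 (27.7% higher, median of all peaks −0.21 against −0.07), whereas equal totals gave 1556 and 1637 and quantile normalization 1697 and 1786 (both 48.7% higher).

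Of the 37 sarcomere peaks 23 fell and 1 rose with junba (31 and 1 adjusted over the list alone, median −1.34, camera adjusted p = 1.7e-09, and adjusted p = 0.36 with an estimated correlation). The myosin heavy chain gene myh7l (−1.97, adjusted p = 0.00015), the promoter of myl7 (−1.92), tnnc1a (−1.58) and ttn.2 (−1.66) were among 13 that kept their calls whichever of the 4 libraries was left out. The riser was a peak 4500 bp from the start of myl7 (1.68). Endothelial and endocardial markers rose in the same libraries, with 7 higher and 0 lower of 13 peaks (8 and 0 adjusted over the list alone, median 1.35, adjusted p = 2.4e-05, and adjusted p = 0.12 with an estimated correlation). The shear-responsive factor genes klf2b (1.97) and klf2a (1.60) and the endothelial factor gene sox18 (1.87) kept their calls in each omission. Those at kdrl, fli1a, fli1b and 1 of egfl7 were called with all libraries, and cdh5 was not called (0.89, adjusted p = 0.12). Immediate early genes other than AP-1 gave 8 higher and 0 lower of 35 peaks (the same adjusted over the list alone, median 0.08, mean 0.41, adjusted p = 0.019, and adjusted p = 0.35 with an estimated correlation). Their median was −0.07 after centring on start sites. The list had been planned as a mark of the stress of isolation, and isolation differs between these groups. Its risers were heat shock genes, hsp70.1, hsp70.2 (2.23) and 3 peaks of hsp70l, with klf9 and the survival gene mcl1a. In contrast, gadd45ba was not called (−0.54, adjusted p = 0.0626). In regeneration, where both groups were sorted, hsp70.1 (2.24) and hsp70.2 (1.65) rose as well, while hsp70l, klf9 and mcl1a were not called. Both comparisons use the same myl7:nucDsRed+ libraries. The rise of this list with junba therefore cannot be assigned to isolation, and its source was not tested.

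No other list passed with junba. AP-1 subunits gave 1 higher peak of 19, fosab (0.85, adjusted p = 0.0058), and 0 lower, the same adjusted over the list alone (median 0.14, adjusted p = 0.42). The peaks of junba and junbb themselves were not called (adjusted p = 0.844 and 0.918 at the largest of each), nor were jun (−0.47, adjusted p = 0.0979) and gata4 (0.80, adjusted p = 0.0675). Cardiac development gave 2 higher and 7 lower of 28, the same adjusted over the list alone (median −0.16, adjusted p = 0.42). The risers were notch1a (2.03), a Notch receptor gene, and socs3a (1.21), and tbx20 (−1.67) and nkx2.5 (−1.65) were among the lower. The cell cycle list gave 5 higher and 2 lower of 30, the same adjusted over the list alone (median 0.33, adjusted p = 0.13). Higher were ccnd1 (1.64), ccnb1 (1.67), pcna, e2f8 and anln, and lower the inhibitor gene cdkn1a (−1.26) and another peak of anln. Calcium handling gave 1 higher (cacnb2a, 1.21) and 5 lower of 16, with 1 and 8 adjusted over the list alone (median −0.42, adjusted p = 0.11). The lower ones were casq2 (−1.79), the sodium-calcium exchanger gene slc8a1a, the triadin gene trdn and the connexin genes gja5a and gja5b. Oxidative metabolism gave 1 higher (hadhaa, 0.96) and 6 lower of 20 (1 and 7 adjusted over the list alone, median −0.37, adjusted p = 0.11), led by ckma (−2.17). Glycolysis gave 2 higher and 8 lower of 31 (2 and 9 adjusted over the list alone, median −0.32, adjusted p = 0.28), with hk2 at 1.90 and ldha at −2.10. Actin protrusion gave 1 higher (wasf3b, 1.34) and 6 lower of 29 including flnca, the same adjusted over the list alone (median −0.32, adjusted p = 0.21). Extracellular matrix gave 2 higher (timp2b and the laminin gene lamb1a at 1.77) and 1 lower (itga5, −1.14) of 16, with 3 and 2 adjusted over the list alone (median 0.33, adjusted p = 0.39). The remaining marker lists had the same counts adjusted over the list alone. Of 5 epicardial and fibroblast peaks 0 were called (median −0.35, adjusted p = 0.98), with col6a1 at 1.04 and pdgfra at −0.74 (adjusted p = 0.109 and 0.226). The leukocyte gene rac2 rose (1.15, list median 0.28, adjusted p = 0.28), and in the erythroid list klf17, a globin regulator, rose (1.76) and the spectrin gene sptb fell (−2.23, list median −0.23, adjusted p = 0.98). The smooth muscle gene smtnb fell (−1.63, list median −1.04, adjusted p = 0.28) and the neural gene elavl4 rose (1.29). Among KEGG terms the lower set was enriched in Cardiac muscle contraction (12 of 28 genes against 2.12 by chance, exact hypergeometric test, adjusted p = 3.31e-05) and Adrenergic signaling in cardiomyocytes (16 of 76, adjusted p = 0.00725). No term passed for the higher set (smallest adjusted p = 0.369).

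Of 94 list peaks called with junba 42 kept their calls in each omission and 52 did not, socs3a, pcna, trdn, kdrl, fli1a, timp2b and mcl1a being kept in 2 of 4 and e2f8 in 1. Peaks named by the rule lost or gained calls as follows. Omitting myl7:nucDsRed+ replicate 1, the adjusted p was 0.113 at wasf3b, 0.0536 at lamb1a, 0.054 at itga5, 0.0684 at cdkn1a and 0.057 at elavl4. Omitting myl7:nucDsRed+ replicate 2, it was 0.245 at itga5, 0.143 at cdkn1a, 0.128 at elavl4 and 0.0506 at tbx5b. It was also 0.0863 at the distal myl7 peak, 0.196 at cacnb2a, 0.321 at hadhaa, 0.154 at rac2 and 0.146 at smtnb. Omitting junba replicate 1, it was 0.0889 at itga5, 0.121 at cacnb2a and 0.19 at hadhaa, while gata4 (0.0425) and the downstream peak of junbb (0.0412) passed. Omitting junba replicate 2, it was 0.0529 at wasf3b, 0.0731 at lamb1a, 0.0502 at itga5, 0.341 at cdkn1a, 0.167 at elavl4, 0.138 at rac2 and 0.144 at smtnb.

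Cardiomyocytes overexpressing junbb were less accessible than uninjured ones at muscle genes such as acta1b, tnnc1a and casq2 and more accessible at endothelial genes such as egfl7 and klf2a, with the same difference in isolation. The acta1b promoter (ENSDARG00000055618, 13:24278735-24279111), a muscle actin gene, fell by 3.09 ± 0.27 (adjusted p = 4.17e-07), from 199 ± 12.7 to 19 ± 2.83 normalized counts (n = 2). The other largest decreases named were ninj2 (−3.40), ldb3a (−2.90), pms1 (−2.67), casq2 (−2.64), tnnc1a (−2.64) and slc8a1a (−2.64). They were followed by ttn.2 (−2.54), xirp1 (−2.48), an actin-binding gene of intercalated discs, and ckma (−2.45). The largest increases named were shank3b (3.18 ± 0.31, adjusted p = 1.02e-06), vap (3.11), marcksl1b (3.01) and egfl7 (2.95), which encodes a factor secreted by endothelium. Next were myct1b (2.75), clec14a (2.75), hsp70.1 (2.69), thoc1 (2.62), znf1028 (2.61) and cacnb2a (2.61). In all 1855 peaks were higher (43.6% of calls, median log2 change 1.42) and 2404 lower (median −1.52). Omitting myl7:nucDsRed+ replicate 1 left 1204 higher and 1618 lower peaks, myl7:nucDsRed+ replicate 2 1256 and 1317, junbb replicate 1 1122 and 1750, and junbb replicate 2 781 and 1285. Equal totals gave 2661 and 1584 (62.7% higher, median of all peaks 0.24 against −0.02). Centring on peaks near start sites gave 1382 and 2914 (32.2% higher, median −0.18), and quantile normalization 2017 and 2137 (48.6% higher).

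With junbb 30 of the 37 sarcomere peaks fell and 1 rose (33 and 1 adjusted over the list alone, median −1.68, camera adjusted p = 1.4e-13, and adjusted p = 0.28 with an estimated correlation). Of these, 19 kept their calls whichever of the 4 libraries was left out, among them the troponin genes tnnc1a, tnnt2a (−1.86) and tnni1b (−2.37), ttn.1 (−2.41) and the myl7 promoter (−1.93). All but 1 of the 13 endothelial and endocardial peaks rose (12 and 0, the same adjusted over the list alone, median 1.84, adjusted p = 1.4e-07, and adjusted p = 0.060 with an estimated correlation). Those at klf2a (2.597), klf2b, sox18 (2.73), fli1a (2.71), kdrl, esama and egfl7 kept their calls in each omission, and a second peak of egfl7, within the gene, was not called (−0.58, adjusted p = 0.319).

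The remaining lists did not pass with junbb. Calcium handling gave 1 higher (cacnb2a) and 7 lower of 16 peaks (2 and 7 adjusted over the list alone, median −0.25, adjusted p = 0.064), all of which kept their calls in each omission. The list passed without myl7:nucDsRed+ replicate 1 (adjusted p = 0.044, and adjusted p = 0.39 with an estimated correlation) and had a median of 0.04 under equal totals. The 7 lower peaks were at casq2, slc8a1a, trdn, gja5a, gja5b and, in 2 peaks, the potassium channel gene kcnh6a. Oxidative metabolism gave 1 higher (hadhaa, 0.83) and 7 lower of 20, led by ckma, the same adjusted over the list alone (median −0.45, adjusted p = 0.064). The adjusted p was 0.044 without myl7:nucDsRed+ replicate 1 and 0.047 without junbb replicate 2 (adjusted p = 0.39 and 0.32 with an estimated correlation). Glycolysis gave 1 higher (hk2, 2.31) and 10 lower of 31, among them pgam2 (−1.84), the same adjusted over the list alone (median −0.31, adjusted p = 0.092). The cell cycle gave 4 higher (ccnd1 at 2.22, ccnb1 at 2.20, top2a and anln) and 0 lower of 30, the same adjusted over the list alone (median 0.32, adjusted p = 0.064, and 0.048 without junbb replicate 1, where an estimated correlation gave an adjusted p of 0.40). The helicase gene mcm2 was not called (−0.68, adjusted p = 0.163). Immediate early genes gave 7 higher and 0 lower of 35 (6 and 0 adjusted over the list alone, median 0.25, adjusted p = 0.064), with hsp70.2 at 2.27 and gadd45ba not called (−0.44, adjusted p = 0.125). AP-1 subunits gave 2 higher, fosab (0.69, adjusted p = 0.0175) and jdp2a, and 0 lower of 19 (0 and 0 adjusted over the list alone, median 0.11, adjusted p = 0.66). The stress factor gene atf3 (−0.57, adjusted p = 0.0858) and all peaks of junba and junbb were not called. Extracellular matrix gave 6 higher, among them the integrin gene itgb5 (1.20), and 1 lower (itga5, −1.95) of 16 (7 and 1 adjusted over the list alone, median 0.39, adjusted p = 0.14). Cardiac development gave 3 higher and 5 lower of 28 (5 and 7 adjusted over the list alone, median −0.10, adjusted p = 0.76). Higher were notch1a (2.062), socs3a (1.24) and gata4 (0.90, adjusted p = 0.0374), and among the lower were nkx2.5 (−2.14) and the natriuretic peptide gene nppa (−1.82). Actin protrusion gave 1 higher (wasf3b, 1.63) and 4 lower of 29, among them zyx (zyxin, −2.08), the same adjusted over the list alone (median −0.01, adjusted p = 0.74). Among other markers the epicardial gene col6a1 was higher (1.31, adjusted p = 0.0416, 0 adjusted over the list alone, list median 0.41, adjusted p = 0.74). In the erythroid list klf17 was higher (2.32) and sptb lower (−1.75, list median 0.28, adjusted p = 0.76), and in the smooth muscle list smtnb was lower (−1.55, list median −0.75, adjusted p = 0.65). The leukocyte list gave 0 calls of 3 (median 0.43, adjusted p = 0.55), and tgfb3 (−0.53, adjusted p = 0.0749), rac2 (0.63, adjusted p = 0.206), cnn1b (0.05, adjusted p = 0.938) and elavl4 (0.81, adjusted p = 0.147) were not called. The lower set was enriched in Cardiac muscle contraction (11 of 28 genes, exact hypergeometric test, adjusted p = 0.000156), Adrenergic signaling in cardiomyocytes (17 of 76, adjusted p = 0.00075) and Glycolysis / Gluconeogenesis (10 of 37, adjusted p = 0.00691). No term passed for the higher set (smallest adjusted p = 0.232).

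Of 107 list peaks called with junbb 58 kept their calls in each omission and 49 did not, jdp2a being kept in 0 of 4, top2a and anln in 1, and socs3a in 2. Peaks named by the rule lost calls as follows. Omitting myl7:nucDsRed+ replicate 1, myl7:nucDsRed+ replicate 2, junbb replicate 1 and junbb replicate 2 in turn, the adjusted p was 0.0537, 0.24, 0.286 and 0.0644 at the distal myl7 peak, 0.0845, 0.0805, 0.0581 and 0.0889 at fosab, and 0.178, 0.0604, 0.125 and 0.159 at gata4. It was 0.232, 0.0656 and 0.49 at col6a1 in the first 3 of these omissions, and 0.467, 0.129 and 0.157 at hadhaa in the last 3. It was 0.159 and 0.201 at smtnb without myl7:nucDsRed+ replicate 2 or junbb replicate 1, and 0.0545 at wasf3b without junbb replicate 2.

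**Figure D3:**
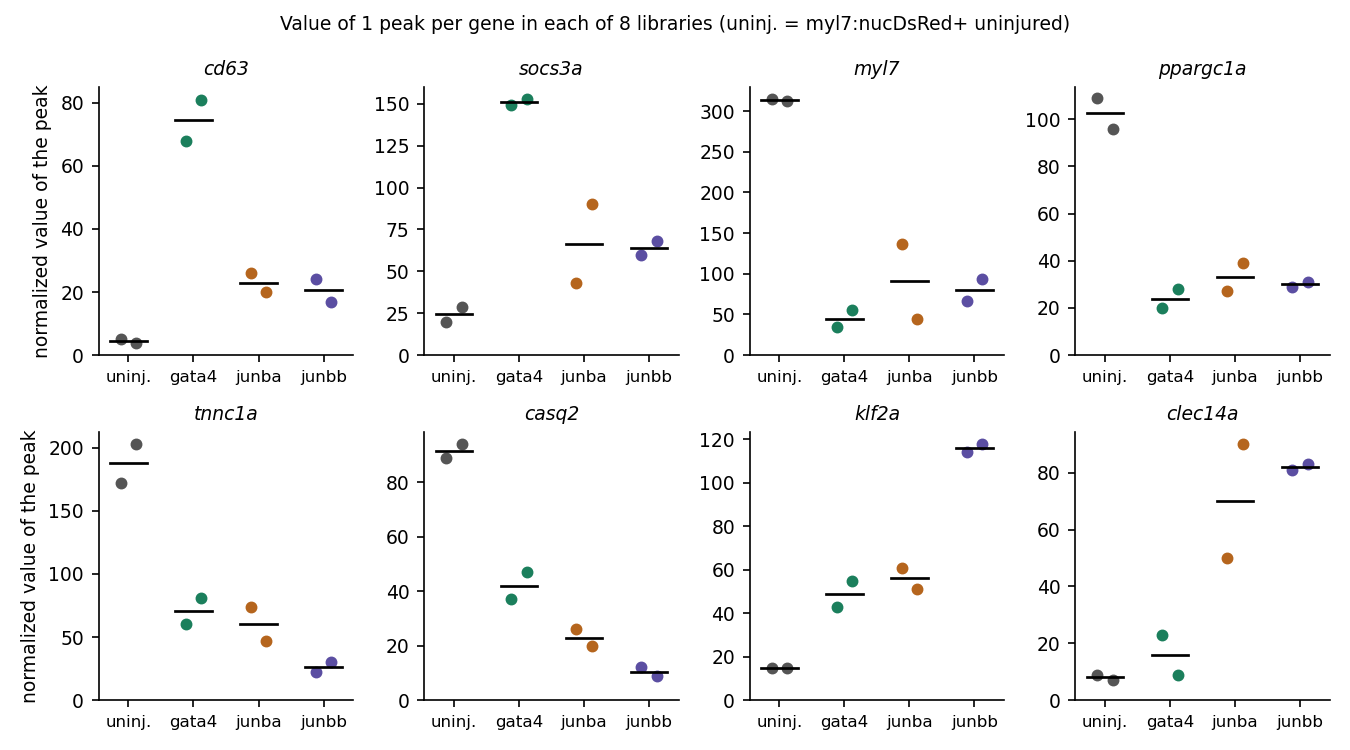
Normalized counts at 1 peak each of cd63, socs3a, myl7, ppargc1a, tnnc1a, casq2, klf2a and clec14a in the 8 libraries of the shared table. Each point is 1 library and the line is the mean of its group.

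Compared directly, junba and junbb libraries, isolated alike, differed at few peaks. The correlation of log2 values was 0.851 between the junba libraries, 0.913 between the junbb libraries and 0.861 to 0.873 between junba and junbb libraries. A peak 2773 bp from cirbpa, a cold-inducible RNA-binding protein gene, was higher with junba (3.33 ± 0.55, adjusted p = 0.0064, 71.5 ± 19.1 against 2.5 ± 0.707, n = 2), as were hsp70l (1.76, adjusted p = 0.0223) and mif4gdb (1.67, adjusted p = 0.0223). A peak near zbtb12.1 was lower (−3.40 ± 0.38, adjusted p = 9.91e-05, 3.0 ± 4.24 against 73.5 ± 3.54, n = 2). By limma 8 peaks were higher and 5 lower, and 1494 had an unadjusted p under 0.05 where 738.8 are expected by chance. Not called were peaks of wbp2nl (1.85, adjusted p = 0.0522), mak16 (1.66, adjusted p = 0.0732) and mast3a (−1.53, adjusted p = 0.113). Nor were those of ypel2a (−1.40, adjusted p = 0.156), st8sia6 (−0.99, adjusted p = 0.136) and the SOX factor gene sox4b (−0.86, adjusted p = 0.156). As lists, sarcomere peaks were higher with junba (37 peaks, 0 called, median 0.35, adjusted p = 1.9e-05, and adjusted p = 0.60 with an estimated correlation). Endothelial and endocardial peaks were lower (13 peaks, 0 called, median −0.64, adjusted p = 0.00060, and adjusted p = 0.21 with an estimated correlation). Of single list members, tnnc1a (1.06, adjusted p = 0.181), klf2a (−0.99, adjusted p = 0.253), cacnb2a (−1.40, adjusted p = 0.188), meis1b (−0.81, adjusted p = 0.245) and wasf3b (−1.10, adjusted p = 0.335) were not called. The other 13 lists tested had an adjusted p of 0.249 or more, and hsp70l gave the one list call. Adjusted over the list alone, sarcomere gave 1 higher, calcium handling 1 lower, immediate early genes 3 higher and endothelial markers 2 lower. Omitting junba replicate 1 gave 126 higher and 201 lower peaks, a sarcomere difference of 0.11 (adjusted p = 0.56) and a call for actin protrusion (median −0.41, adjusted p = 0.024, and adjusted p = 0.88 with an estimated correlation). Then wbp2nl (0.0483), mak16 (0.00158), mast3a (0.0148), st8sia6 (0.0332), ypel2a (0.0409), meis1b (0.0268) and cacnb2a (0.0349) passed. Omitting junba replicate 2 gave 18 and 27 peaks, and wbp2nl passed (0.0347) and mif4gdb did not (0.0599). Omitting junbb replicate 1 gave 0 and 1 (adjusted p 0.38 at mif4gdb, 0.247 at cirbpa and 0.0907 at hsp70l). Omitting junbb replicate 2 gave 1 and 1 (0.0731 at mif4gdb, 0.195 at cirbpa and 0.544 at hsp70l), and equal totals gave 4 and 6 (40.0% against 61.5% higher, median of all peaks −0.18).

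The 3 comparisons overlapped, and all 3 use the same 2 myl7:nucDsRed+ libraries, which alone produces overlap and cannot be split between them. Of the regeneration higher peaks 319 (17.5%) were also higher with junba, socs3a, ccnd1 and klf2a among them, where independence gives 186.4 and a simulation with shared controls and no effects 568. With junbb the number was 395 (21.7%; independent 228.2, simulated 655). Of the regeneration lower peaks 449 (46.0%; 154.9 and 479) were also lower with junba and 465 (47.6%; 159.0 and 485) with junbb, ppargc1a and tbx20 among both. The simulated counts take the observed numbers of peaks by smallest p, without a threshold, so they are not counts of calls. They leave out every effect and the independent counts leave out the shared controls, so neither gives the number shared through an effect. The covariances of log2 change were 0.268 for junba and 0.312 for junbb against 0.0724 and 0.0723 simulated, differences of 0.195 and 0.240. Between junba and junbb 1097 higher and 1737 lower peaks were shared (72.4% and 74.2% of the junba calls), where independence gives 190.2 and 381.0 and the simulation 575 and 942, and the covariance was 0.772 against 0.0724 simulated. The junba share was 26.1% and 26.8% without gata4:EGFP+ replicates 1 and 2 and 11.1% without junba replicate 2. The junbb share was 33.9% and 37.2% without gata4:EGFP+ replicates 1 and 2, 13.7% and 11.4% without junbb replicates 1 and 2.

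Inducing A-Fos in injured cardiomyocytes changed no peak past the threshold. Of 6012 peaks tested with limma, 0 were higher and 0 lower, with 200 at an unadjusted p under 0.05 against 300.6 expected and a smallest adjusted p of 1. The 95% interval of a log2 change in this unpaired fit reached a median of 0.72 to either side. That interval is not adjusted for the number of peaks, so a call at a typical peak needed a larger change. With a replicate block 0 peaks were called as well, with 400 at an unadjusted p under 0.05. In simulated data of this depth 73.1% of 4-fold and 11.6% of 2-fold changes were recovered. The peaks of smallest p were csmd2 (1.07 ± 0.30), dvl3b (0.70), a Dishevelled gene, the glycine methyltransferase gene gnmt (0.71), rb1cc1 (0.79) and prss16 (0.62) in the higher direction. In the lower direction they were pkd2 (−0.86), the polycystin 2 gene, fam122b (−0.78), ing3 (−0.68), aacs (−0.67) and mycbp2 (−0.62), and each had an adjusted p of 1. AP-1 subunit peaks were not called (13 peaks, median 0.15, adjusted p = 0.66), with fosb at 0.53 ± 0.33 and junba at −0.14 ± 0.30. Of the 16 lists 12 had at least 2 peaks and none passed (adjusted p from 0.659 to 0.918). The median log2 change was −0.10 for actin protrusion (11 peaks), −0.17 for cardiac development (8), 0.04 for the cell cycle (22), 0.10 for oxidative metabolism (11) and −0.04 for glycolysis (16). It was 0.06 for immediate early genes (29), −0.08 for calcium handling (7), 0.11 for extracellular matrix (4), −0.13 for leukocyte (5), 0.38 for sarcomere (2) and −0.22 for endothelial markers (2). Only 2 sarcomere peaks were tested here against 37 in the shared table, so most sarcomere peaks could not be followed. No list member passed when adjusted over the list alone, the epicardial list held 1 peak and the erythroid, smooth muscle and neural lists 0. Equal totals over tested peaks moved the median change of all peaks from 0.00 to −0.24 with 402 at an unadjusted p under 0.05, and called 0.

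At the peaks that rose in regeneration, A-Fos was accompanied by a small shift. The 334 tested peaks of this table that overlap a regeneration higher peak had a median log2 change of −0.05 against 0.00 for the others (difference −0.053, 58.7% against 50.1% below 0, camera adjusted p = 0.0415, and adjusted p = 0.704 with an estimated correlation). Only 333 of the 1818 regeneration higher peaks overlap a tested peak here, so most could not be followed. The 374 peaks overlapping regeneration lower peaks differed by 0.021 (adjusted p = 0.544). Without A-Fos(-) replicate 1 the difference at regeneration higher peaks was 0.014 (adjusted p = 0.93) and without A-Fos(-) replicate 3 it was −0.123. It lost its call without A-Fos(+) replicate 2 (−0.053) and when the regeneration peaks were called with fewer libraries. The difference was then −0.087 and −0.035 without gata4:EGFP+ replicates 1 and 2, and −0.009 and −0.059 without myl7:nucDsRed+ replicates 1 and 2.

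**Figure D4:**
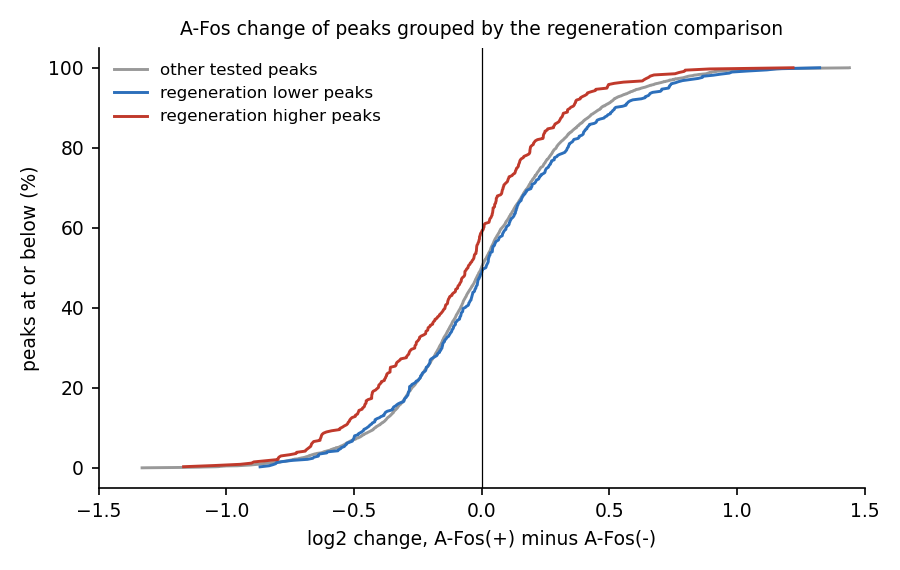
Cumulative distribution of the log2 change in accessibility with A-Fos, at peaks that overlap a regeneration higher peak, at peaks that overlap a regeneration lower peak and at all other tested peaks.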

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

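Of the tests in this part, those of cell composition, of signal and location, of the leukocyte list and of transgene copies were chosen only after the results were seen. The direct comparison of junba and junbb tested whether the effects of both differ, and 8 peaks higher with junba and 5 lower passed. The log2 difference was 3.33 at cirbpa, 1.67 at mif4gdb, 1.76 at hsp70l and −3.40 at zbtb12.1. As lists, the median difference was 0.35 for sarcomere peaks (0.11 without junba replicate 1, adjusted p = 0.56) and −0.64 for endothelial and endocardial peaks. Without junbb replicate 1 the count was 0 higher and 1 lower, and without junba replicate 1 it was 126 and 201, so the number differing is set by single libraries.

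Sarcomere peaks as a list were lower and endothelial peaks higher in both junb groups than in sorted uninjured cells, with the preset correlation but not with an estimated one (adjusted p = 0.36 and 0.12 for junba, 0.28 and 0.060 for junbb), and 13 of 37 and 6 of 13 were not called for junba. Marker lists were also compared because a lower share of cardiomyocytes might raise every other cell type alike. For junbb the other 5 marker lists lay below the endothelial list by 1.43 (difference −1.43, 95% bootstrap interval over peaks −2.63 to −1.02, and −1.51, −2.52 to −0.78, over peaks of low baseline). For junba that difference was −1.24 (−2.09 to −0.079), and −0.90 (−2.09 to 0.10) over the 8 low-baseline peaks of other lists, where the interval includes 0. The endothelial list was singled out after it had risen, and the intervals resample peaks and not libraries. These values therefore cannot decide for or against such a lower share. A larger share of endothelial or endocardial cells after gradient isolation and an effect of junb overexpression on these genes cannot be told apart, since no gradient-isolated library without overexpression is in the table. Between junba and junbb, isolated alike, the endothelial list (−0.64, interval over peaks −0.99 to −0.31) and the sarcomere list (0.35, 0.247 to 0.500) moved in opposite directions, but a stronger effect of junbb would do the same, the sarcomere difference was 0.11 (adjusted p = 0.56) without junba replicate 1, and neither list passed with an estimated correlation (adjusted p = 0.21 and 0.60).

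Regeneration higher peaks lay away from start sites and outnumbered lower ones. Among peaks with a mean of at least 30 the odds ratio was 0.175 (95% interval 0.134 to 0.227), so the distal location of higher peaks is not confined to low values. Those higher peaks still had less signal than peaks not called (median value 41.6 against 53.1). The cut-off did not equalize signal, so it cannot exclude that low signal of distal peaks adds to their location. Whether low signal makes the excess of higher calls cannot be told: among peaks whose mean log2 value over both groups reached that of 30, 40.1% of 758 calls were higher (36.6 to 43.7%), but 41.5%, 52.3%, 61.1% and 59.6% without gata4:EGFP+ replicates 1 and 2 and myl7:nucDsRed+ replicates 1 and 2. The gata4:EGFP+ cells were sorted on the reporter, which should remove leukocytes without it, and with 3 peaks (median 0.22) the leukocyte list is too small to show whether any remained. A change in distal regulatory sites of regenerating cardiomyocytes stays among the open explanations, as does the difference in the population sorted.

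Signal stood out at sequences in use as transgene promoters. At myl7 the promoter peak changed by −2.70 in regeneration, more than any of the 36 other sarcomere peaks (next −1.94), at ubb the lowest junb library exceeded the highest sorted library 3.02 times, and at a peak 9594 bp upstream of the gata4 promoter peak (20:52977067-52977491) both gata4:EGFP+ libraries held 275 and 227 normalized counts against 14 and 22 in myl7:nucDsRed+, 0 and 0 in junba and 8 and 9 in junbb libraries. That last change (3.49 ± 0.38, adjusted p = 1.11e-05) was exceeded by 1 of 1818 higher peaks, or 0.0550%, while the gata4 promoter peak itself was not called. Reads from transgene copies may add to each of these 3 peaks, but a change at the endogenous sequence would look alike and the reads that would tell are not used here, so these cannot be told apart. The sarcomere median without the myl7 promoter peak was −0.71, but leaving out 1 of 37 peaks can hardly move a median. The list test was not rerun without that peak.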

How the results depend on the processing

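Among the alternatives here, array weights, centring on peaks near a start site, leaving out wide peaks, leaving out A-Fos libraries by number, and the omissions behind the shares of regeneration peaks and behind the regeneration peak sets were tests chosen only after the data were seen. The AP-1 motif results and their alternatives were not run, for lack of a genome sequence. No named peak reversed its direction with a call. The totals that follow count every named peak, also those not called, which had no call to lose. For junba against junbb the named calls were at cirbpa, mif4gdb, hsp70l and zbtb12.1, and all but that at zbtb12.1 were lost in some setting. Calls were lost in at least 1 setting by 16 of 51 named regeneration peaks, 11 of 55 for junba, 7 of 53 for junbb and 3 of 45 for junba against junbb, and 11, 5, 1 and 1 of these only when a library was left out. Such an omission leaves 1 library in a group of the shared table, which is then assumed to vary like the others, so lower power is part of its construction. In simulated data with fewer changed peaks than were called here, 4-fold changes were recovered at about 70.4% and 2-fold changes at 11.7% for regeneration. Depth, the number of libraries and the number of changed peaks were not varied, so the cause of these shares was not tested.

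Pseudocount 1 gave 1145 higher and 593 lower regeneration peaks, 4 higher peaks for junba against junbb, an A-Fos difference of −0.056 at regeneration higher peaks (adjusted p = 0.050) and shares of 25.9% for junba and 30.3% for junbb. Pseudocount 20 gave 31 peaks for junba against junbb (14 and 17) and shares of 12.2% and 16.6%. A mean of at least 30 over all 8 libraries of the shared table, which tests fewer peaks, gave 352 and 488 for regeneration, 864 and 1113 for junba, 896 and 1154 for junbb and 7 (4 and 3) for junba against junbb, and no filter gave 8 lower for the last. Equal totals gave 300 lower regeneration peaks, 1584 lower junbb peaks and 4 higher for junba against junbb. Fitting only the 2 groups compared gave 2825 and 1882 for regeneration, 917 higher for junba and 3 lower for junba against junbb. Array weights gave 1576 lower and centring 429 lower regeneration peaks. Quantile normalization gave an A-Fos difference of −0.047 (adjusted p = 0.13). For these the cause was not tested, apart from the number of peaks tested. With an estimated correlation 0 lists passed in regeneration, junba, junbb and junba against junbb, where 4, 3, 2 and 2 passed with the preset one. The estimate was −0.026 for the endothelial list and 0.0039 for glycolysis, below the preset 0.01. Camera p still rose, from 1.92e-08 to 0.00401 for endothelial peaks with junbb and from 0.00185 to 0.0283 for glycolysis in regeneration. A higher correlation does not explain that rise. For the other lists that passed the estimate lay above 0.01, from 0.011 for immediate early genes to 0.24 for sarcomere. Beyond this the cause was not tested.

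Leaving out single libraries gave 328 to 1075 higher and 129 to 357 lower regeneration peaks, 882 to 1685 and 1039 to 2706 for junba, 781 to 1256 and 1285 to 1750 for junbb, and 1 to 327 (0 to 126 and 1 to 201) for junba against junbb. A-Fos kept 0 and 0, and the A-Fos difference ran from −0.123 to 0.014 at regeneration higher peaks, the reversed value being 0.014 without A-Fos(-) replicate 1 (adjusted p = 0.93), and from −0.010 to 0.090 at lower ones. Shares ran from 11.1 to 26.8% for junba and 11.4 to 37.2% for junbb. The cause was not tested. Leaving out both A-Fos libraries of number 3 called 1 higher peak.

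Samples of the same number were checked for pairing by the correlation of their residuals across peaks, and peaks are not independent replicates. In the A-Fos table these were 0.280, 0.256 and 0.082 for the same number and −0.24 to 0.03 otherwise, and in the shared table −0.03 to 0.02 for the same number. The labels name no pairing, so the unpaired fit was kept. With a replicate block the A-Fos comparison called 0 peaks with 400 at an unadjusted p under 0.05, regeneration 1785 higher and 959 lower, and junba against junbb 10 and 7.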

Other observations

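The test of A-Fos at junb lower peaks and the loci named here were chosen only after the values were seen, and the count of sample splits was planned. At the start of chromosome 7 all 7 tested peaks of the first 10000 bp were lower in gata4:EGFP+ than in myl7:nucDsRed+ libraries. At each of them the junba and junbb libraries, which are also uninjured, lay below the myl7:nucDsRed+ libraries as well. Normalized counts there ran from 0 to 205 in gata4:EGFP+, 98 to 745 in myl7:nucDsRed+, 20 to 420 in junba and 27 to 283 in junbb libraries. At 7:6452-6869 both gata4:EGFP+ libraries were listed at 0, with 348 and 316 in myl7:nucDsRed+, 94 and 63 in junba and 103 and 57 in junbb libraries (adjusted p = 2.77e-11).

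A hypothesis that A-Fos raises accessibility at peaks lower in the junb libraries was tested at 352 peaks that are lower with junbb and overlap a tested A-Fos peak. Those libraries also differ from their controls in isolation, so overexpression need not be what lowers these peaks. The 352 peaks had a median log2 change with A-Fos of 0.24 (0.25 above the other peaks), and 34.1% lay below 0 against 51.6% of the others. The median difference ran from 0.152 to 0.323 when each A-Fos library was left out. Camera gave an adjusted p of 5.09e-08 with the preset correlation. With an estimated correlation p was 0.100 (adjusted p = 0.2503), and 0.0397 with a replicate block, so the hypothesis stays open. The 327 peaks lower with junba had a median of 0.18 (camera, adjusted p = 5.55e-06 with the preset and adjusted p = 0.2503 with an estimated correlation).

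Of the 10 splits of the A-Fos libraries into 3 against 3, 7, the real one included, gave at least the 200 peaks at an unadjusted p under 0.05 of the real one, and the highest other gave 593. These splits are too few for a share under 0.05. The split with 593 sets A-Fos(+) replicates 1 and 3 with A-Fos(-) replicate 1 against the rest.

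The ubb promoter peak, one of the peaks of high signal in the A-Fos table (rank 36 by mean), held 785, 2830 and 491 normalized counts in A-Fos(+) and 402, 1887 and 567 in A-Fos(-) replicates 1 to 3 (log2 change 0.44 ± 0.69, adjusted p = 1).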
